A study of Mus musculus with 16 samples.

How the data were processed

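The deposited table holds whole-number read counts for 52997 gene symbols in 16 mouse libraries, with 1 column per library and no column combining libraries. Per the submitters' processing notes, the authors aligned reads with STAR 2.5.4 to genome build mm10 and counted them with featureCounts. The featureCounts version, the annotation and the strand setting are not given in the sources used here. Per the labels' protocols, polyadenylated RNA was primed with oligo(dT), amplified, and made into libraries by transposon fragmentation, which does not mark strand. Reads of overlapping or antisense genes therefore cannot be fully told apart. Near-identical T cell receptor (TCR) segments can also share reads, whatever the strand. The labels' protocol and the series' design text give different numbers of sorted cells per library, so no cell number is used here.

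Total counts ran from 1986700 to 9116800 in the 10 regulatory T cell (Treg) libraries and from 5095999 to 7075420 in the 6 whole muscle libraries. A count of 0 allows up to 3 counts per library, which is 1.51 CPM (counts scaled by library total) in the shallowest library and 0.329 CPM in the deepest. Intervals and floors cover counting error only, because amplified reads carry no molecular identifiers. Within each group the libraries differed by far more than sampling noise (chi-square per degree of freedom between 6.43 and 35.7), so none was counted as a duplicate.

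Changed genes were found with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM scaling, estimateDisp, glmQLFit with robust dispersion, and glmQLFTest with Benjamini-Hochberg adjustment, at an adjusted p under 0.05 and with no minimum fold. The 10 Treg libraries shared 1 fit of 5 groups with 2 libraries each (13188 genes tested, 5 residual degrees of freedom). The 6 whole muscle libraries had their own fit of 2 groups with 3 libraries each (12377 genes, 4 residual degrees of freedom). Group levels are TMM-scaled CPM as mean ± SD over libraries, and fold changes are log2 values with an SE approximated from the test statistic. Whether replicates came from separate animals or pools is not stated in the labels, so p-values measure the spread between these samples, which may be technical. That spread is estimated over all groups of a fit, not over the compared groups alone.

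Of 28 gene lists fixed before the data were examined, 21 applied to Tregs and 23 to whole muscle. Lists with at least 3 tested members entered camera of limma 3.58.1 (17 lists in Tregs, 20 in whole muscle) with a preset correlation of 0.01. Each test was repeated with an estimated correlation and with fry. With an estimated correlation, 6 of 11 called lists held in the WT tissue comparison and 5 of 13 in the Tg tissue comparison, and 0 held elsewhere. Named genes follow a rule fixed before the data were examined: the 10 higher and 10 lower genes with the largest change among called genes with mean log2 CPM of at least 4 and no overlap of library values, up to 4 called and 2 uncalled members of each list, and Foxp3, Il2ra, Cd4, the Vβ8 segments and the leading TCR segments always. In whole muscle, Myh3, Pax7, Col1a1 and Lyz2 were added. Unnamed genes, pseudogenes and receptor segments were left out of the first part. Some genes that the rule names are not reported here, though counts of genes include them.

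The procedure was tested on simulated data with 200 changed genes per comparison. These were drawn from genes with a mean of at least 5 CPM, so recovery of rarer genes was not measured. All groups were simulated from a common mean and a common dispersion per gene, with changes in only the first compared group. The real groups differed in spread (chi-square per degree of freedom between 6.43 and 35.7). The simulated rates may therefore not carry over to the real comparisons. In the WT tissue simulation (13188 genes simulated), 37% of 2-fold and 85% of 4-fold changes were recovered and 7.6% of calls were false. In the simulation of injured against uninjured Tg spleen (13188 genes simulated), 36% and 79% were recovered and 8% of calls were false. In the simulation of injured Tg against WT spleen, 40% and 84% were recovered and 8.8% of calls were false. In the whole muscle simulation (12377 genes simulated), 59% and 92% were recovered and 5.6% of calls were false.

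Alternatives fixed before the data were examined were relative log expression scaling, no filter or a filter at 5 CPM, DESeq2 1.42.0, limma-voom, no robust dispersion, a replicate block, removal of the variable, diversity and joining segments of TCR and immunoglobulin genes, thinning to the smallest library, fits of the compared groups only, a minimum log2 fold of 1, removal of the 20 most abundant whole muscle genes, and leaving out each library in turn. The limma-voom alternative was first run with robust empirical Bayes and then, as planned, without it. Both are given, the robust version as an alternative chosen after seeing the data. Coordinates are from GENCODE M21 on GRCm38, the assembly also called mm10.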

Results

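RNA was measured in Tregs, the Foxp3-expressing T cells that restrain immune responses, and in whole skeletal muscle of mice with (Tg) or without (WT) a transgenic TCR cloned from a muscle Treg. Cardiotoxin, a venom toxin that kills muscle fibres, was used to injure muscle. Tregs were sorted 3 days after injury from muscle and spleen of both genotypes, and also from uninjured Tg spleen, with 2 libraries per group. The injury state of the WT spleen group is taken from the series' design text. Tregs of Tg mice were sorted as Vβ8-positive and those of WT mice as total Tregs, so the sort gate differs between genotypes. Whole muscle was collected 8 days after injury, with 3 libraries per genotype. Total counts were 4625354 and 9116800 in WT muscle Tregs, 2899946 and 4438454 in Tg muscle Tregs, 1986700 and 4502813 in WT spleen Tregs, 4174703 and 4230359 in injured Tg spleen Tregs, and 2883691 and 3709503 in uninjured Tg spleen Tregs. They were 6911679, 6782174 and 5095999 in WT and 6082363, 6499968 and 7075420 in Tg whole muscle.

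The transgene was checked first. Trbv13-2, a Vβ8 segment (chromosome 6, 41121396 to 41121832), made up 98.16% ± 0.35 (SD, n = 2) of Trbv counts in Tg muscle Tregs, 97.06% ± 0.7 in injured and 97.62% ± 0.28 in uninjured Tg spleen Tregs, against 4.42% ± 0.41 in WT muscle and 10.16% ± 2.34 in WT spleen Tregs. Trav9-4 (chromosome 14, 53676141 to 53676630) made up 87.34% ± 4.67 of Trav counts in Tg muscle Tregs, 66.47% ± 6.91 in injured and 66.54% ± 2.33 in uninjured Tg spleen Tregs. In WT it made up 3.84% ± 0.13 in muscle and 5.16% ± 0.05 in spleen. Because only Tg Tregs were sorted as Vβ8-positive, the gate itself favours Vβ8 segments in Tg, and the Trbv13-2 share is no independent check. The gate did not select on Trav9-4 directly, but Trav9-4 was picked as the Trav segment with the highest mean in Tg Tregs. That it leads there was fixed by this choice, whereas the size of its share was not. Counts of single segments can be shared with close relatives.

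The first comparison asked how Tregs of injured WT muscle differ from those of the spleen. Muscle Tregs carried more transcripts of effector genes (25 of 28 tested) and fewer of lymphoid homing genes (16 of 19 tested). Areg, the growth factor amphiregulin (chromosome 5, 91139599 to 91148432), was 168 ± 40.6 CPM in muscle against 2.68 ± 0.39 in spleen (SD, n = 2), a log2 fold change of 5.91 ± 0.60 (SE). Il10, an anti-inflammatory cytokine, rose by 4.99 ± 0.39, Gzmb, a cytotoxic protease, by 4.95 ± 0.33, and Ctla4, an inhibitory receptor, by 2.25 ± 0.14 on the log2 scale. Foxp3 (chromosome X, 7573644 to 7595245) rose by 0.68 ± 0.13 (adjusted p = 0.00254), whereas Il2ra was 707 ± 87.3 CPM against 695 ± 82.1 (adjusted p = 0.947). In all, 2143 genes changed, 1237 higher and 906 lower in muscle.

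Among the genes with the largest changes were Cdkn1a, a cell cycle inhibitor, with a log2 fold change of 6.21, Anxa1 with 6.19, Mmp25 with 5.57, Ctla2a with 5.53, Rgs2 with 5.27 and Lmna, encoding lamin A, with 5.20. Hspa1a, an inducible heat shock protein, had 0 counts in both WT spleen libraries and was at least 90.6-fold higher in muscle against a floor of 3 counts per library. The largest decreases included Gata1 at -4.86, Igfbp4 at -4.73, Parp8 at -4.53, Treml2 at -4.29, Atp1b1 at -4.14, Bcl2, a survival factor, at -4.07, Nsg2 at -3.97 and Gpr83 at -3.60.

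Of 28 tested genes of the tissue Treg effector list, 25 rose and 0 fell (25 and 0 adjusted over the list alone; adjusted p = 0.0271 with an estimated correlation), among them Icos (2.67), Rora (2.39) and Irf4 (2.31). Pdcd1 (0.47, adjusted p = 0.42) and Lag3 (0.44, adjusted p = 0.596) did not pass. Of 19 lymphoid homing and quiescence genes, 16 fell, including the chemokine receptor Ccr7 (-1.90) and Evl (-3.08), while S1pr1 was at -0.30 (adjusted p = 0.19). Of 22 chemokine receptor and integrin genes, 15 rose, such as Itgae (3.11), Ccr4 (2.31) and Cxcr3 (2.07), and 2 fell, including the follicle-homing receptor Cxcr5 (-2.87). Of 24 TCR-induced genes, 17 rose, with Fosl2 (4.59), Junb (2.60) and Cd69 (2.02), and 1 fell. Rel (0.29, adjusted p = 0.271) and Myc (-0.54, adjusted p = 0.21) did not pass. The type 1 and cytotoxic list had 5 of 12 genes higher (8 adjusted over the list alone), among them Il12rb1 (1.65). The latter 4 lists gave an adjusted p between 0.0255 and 0.0271 with an estimated correlation. In tests chosen after seeing the data, the type 1 and cytotoxic list gave an adjusted p = 0.117 with an estimated correlation without WT muscle Treg replicate 2, and without WT spleen Treg replicate 2 this list and the chemokine receptor and integrin list each gave an adjusted p = 0.0539 with an estimated correlation.

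Genes known to respond to tissue dissociation and heat also rose in muscle, 17 of 23 (adjusted p = 0.0255 with an estimated correlation), including Fos (4.20), Dusp1 (3.58) and Klf6 (1.75), with Socs3 at -0.21 (adjusted p = 0.617). Muscle and spleen need different preparation, so this moves with every muscle against spleen difference. Glycolysis genes rose in 9 of 16 cases, with Tpi1 (1.83), Pkm (1.23) and the lactate exporter Slc16a3 (2.33), but the list's adjusted p = 0.0988 with an estimated correlation. In the cell cycle list 6 of 39 rose, such as Mki67 (1.49), Mcm2 (0.98) and Mcm6 (0.97), with an adjusted p = 0.37 with an estimated correlation, and 2 of 39 rose without WT spleen Treg replicate 2. In the interferon list 7 of 30 rose (18 adjusted over the list alone), such as Bst2 (1.35), with an adjusted p = 0.456 with an estimated correlation. Without WT muscle Treg replicate 2, 3 of 30 rose and the list's median was 0.31 against 0.94, and without WT spleen Treg replicate 2, 1 of 30 rose. Of 10 B cell genes 2 fell in muscle, including Ighd (5.67 ± 0.995 CPM against 20.2 ± 0.0492 in spleen), with Ighm at 1560 ± 154 against 1440 ± 212 (adjusted p = 0.606), Igkc at 26.8 ± 13.3 against 893 ± 1240 (adjusted p = 0.154), and an adjusted p = 0.37 for the list with an estimated correlation. Of 16 macrophage and monocyte genes 2 fell, including Apoe (8.52 ± 3.74 against 39.7 ± 0.946 CPM), and 1 rose, with Ctss at 354 ± 143 against 319 ± 21 (adjusted p = 0.694), and an adjusted p = 0.489 for the list with an estimated correlation. Of the muscle fibre list, Neb rose (1.48) while Ttn (-1.18) and Eno3 (-1.94) fell. Without WT spleen Treg replicate 2, in which Igkc was high, 887 genes were called, and without WT muscle Treg replicate 2, which had the fewest genes detected (17081), 1347 were called. A fit of these 2 groups alone called 1046.

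The same question in Tg mice compared muscle with spleen Tregs after injury. Areg (6.80 ± 0.60), Il10 (5.92 ± 0.43), Fosl2 (4.78 ± 0.21) and Gzmb (3.31 ± 0.30) rose on the log2 scale, and Tcf7, a transcription factor of resting T cells, fell to 4.35 ± 4.42 CPM from 165 ± 2.47 (SD, n = 2). Foxp3 rose by 0.90 ± 0.13 and Il2ra by 1.52 ± 0.17 (adjusted p = 3.59e-05), while Cd4 was 675 ± 27.6 against 673 ± 52.5 CPM (adjusted p = 0.994). In all, 973 genes changed, 637 higher and 336 lower. Hspa1a (8.22), Pcsk1 (5.53), Cdkn1a (4.95), Fos (4.76), Rgs2 (4.54), Ctla2a (4.39) and Ppp1r15a (4.35) were among the largest increases. Igfbp4 and Slc40a1, the iron exporter ferroportin, had 0 counts in Tg muscle Tregs and were at least 85.6-fold and 41.8-fold higher in spleen against 3 counts per library. In the same comparison 5 of 16 macrophage and monocyte genes were lower in muscle, such as C1qa (0 against 13.4 ± 1.66 CPM). Whether the spleen counts of Slc40a1 came from Tregs or from macrophage RNA in the sort was not tested. Tbc1d4 (-6.08), Aff3 (-4.56), Gpr83 (-3.85), Cxcr5 (-3.78), Bcl2 (-3.57) and Nsg2 (-3.46) fell.

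In Tg Tregs 19 of 28 effector genes rose (25 adjusted over the list alone), with Irf4 (1.99), Icos (1.85) and Rora (1.57), and Klrg1 at 1.14 (adjusted p = 0.136). TCR-induced genes rose in 18 of 24 cases, with Nr4a1 (3.88), Junb (2.70) and Cd69 (2.02), and 11 of 19 lymphoid homing genes fell, with Ccr7 at -2.23. These 3 lists had an adjusted p of at most 0.0315 with an estimated correlation. Chemokine receptor and integrin genes rose in 9 and fell in 2 of 22 cases, with Itgae (1.97), Ccr4 (1.05) and Itga4 (-2.53), and an adjusted p = 0.0773 with an estimated correlation. Dissociation and heat shock genes rose in 17 of 23 cases, with Jun (3.48), and an adjusted p = 0.0126 with an estimated correlation. Glycolysis genes rose in 9 of 16 cases (Pkm 1.27, Tpi1 1.22; adjusted p = 0.0665 with an estimated correlation) and interferon genes in 6 of 30 (20 adjusted over the list alone; Oas2 2.30, Bst2 1.32; adjusted p = 0.215 with an estimated correlation). Macrophage genes fell in 5 of 16 cases, with C1qb (-5.06) and Apoe (-2.55), and an adjusted p = 0.117 with an estimated correlation. Leaving out 1 library left between 452 and 640 calls.

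Of the 2143 genes changed in WT, 1985 moved the same way in Tg (92.6%, 95% exact binomial interval 91.4 to 93.7%, genes not being independent), against 67.2% of genes not called in WT. The comparisons share no libraries. Both called 496 genes higher, where independent lists would share 59.75, and 218 lower, where they would share 23.08, and 1 gene was called in opposite directions.

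**Figure D1:**
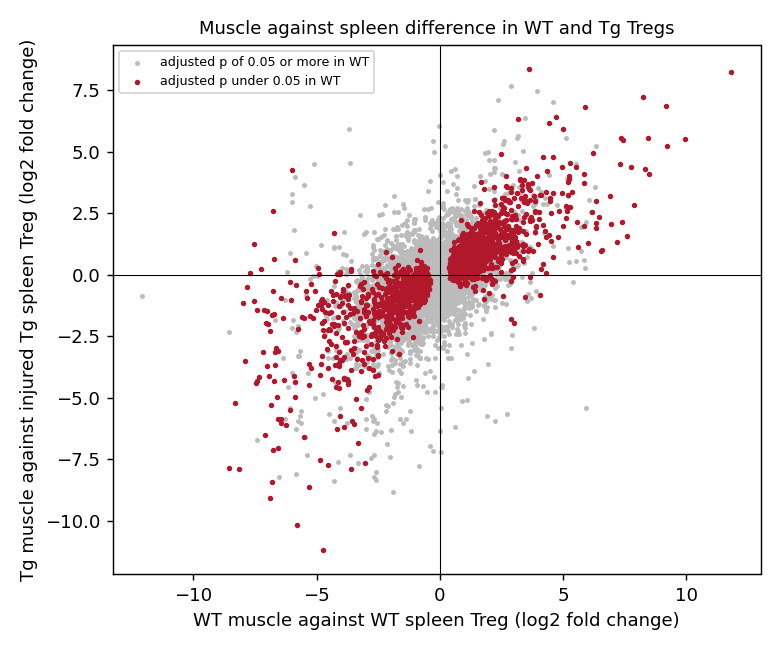
Log2 fold change of muscle against spleen Tregs in WT (horizontal) and Tg (vertical) for 13188 tested genes, 1 point per gene, with the 2143 genes called in WT in red. Red points fall mostly in the lower left and upper right, where 1985 of them lie.

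The third comparison set Tg against WT Tregs within injured muscle. Some TCR genes were higher in Tg: Trbv13-2 was 4870 ± 237 CPM against 18.8 ± 4.5 in WT (SD, n = 2), Trav9-4 1350 ± 207 against 11 ± 0.889, Trbc2 7370 ± 416 against 566 ± 47.9 and Trac 3150 ± 411 against 1040 ± 180. Foxp3 was 2230 ± 114 against 2030 ± 207 CPM (adjusted p = 0.836) and Ctla4 2190 ± 73.9 against 2040 ± 424 (adjusted p = 0.896). In all, 42 genes changed. Of these, 16 were TCR or immunoglobulin genes, constant regions included, 9 higher and 7 lower in Tg, and 26 were others, 7 higher and 19 lower in Tg. Rel, a transcription factor subunit of the NF-κB family, rose by 1.27 ± 0.16, and Nckap5 (2.86), Ttn (2.28), Casp4 (1.85), Mical3 (1.38) and Nav2 (1.13) also rose. The purinergic receptor P2rx7 fell by 2.31 ± 0.21, with Gbp2b (-4.11), Prg4 (-2.57), Gpr83 (-2.32), Angptl2 (-1.71), Fam49a (-1.69), Ckb (-1.67), Ccr7 (-1.56), Abcb8 (-1.41) and Itga4 (-1.40).

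Of the 28 effector genes 0 passed (7 higher and 2 lower adjusted over the list alone; adjusted p = 0.525 with an estimated correlation), with Icos at 0.33 (adjusted p = 0.604) and Ccr2 at -0.16 (adjusted p = 0.945). Of 22 cholesterol synthesis genes 2 fell (5 adjusted over the list alone), including Hmgcs1 (-1.05). The list's adjusted p = 0.0763 with an estimated correlation. Of 24 TCR-induced genes 24 had a positive log2 value, but only Rel passed in this fit (5 adjusted over the list alone), and that list also gave an adjusted p = 0.0763 with an estimated correlation. Without WT muscle Treg replicate 2, a test chosen after seeing the data, 3 of them rose, with an adjusted p = 0.0187 with an estimated correlation, and the median of the interferon list moved from -0.06 to 0.93 (adjusted p = 0.133 with an estimated correlation). The count moved to 361 without WT muscle Treg replicate 1, to 88 without WT muscle Treg replicate 2, to 25 without Tg muscle Treg replicate 1, and to 101 with DESeq2. With the variable, diversity and joining segments removed and the constant regions kept, 16 genes were called.

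In the spleen after injury, 7 of 28 effector genes were higher in Tg than in WT Tregs and 0 lower, and the list gave an adjusted p = 0.0815 with an estimated correlation. Klrg1, a marker of activated Tregs, was 437 ± 11.3 CPM in Tg against 65 ± 23.9 in WT (SD, n = 2), Gzmb 181 ± 25.6 against 39.5 ± 17.6, and Il1rl1, the IL-33 receptor, 121 ± 27.8 against 28.9 ± 11. Il2ra, the IL-2 receptor alpha chain, fell by 0.91 ± 0.17, and Foxp3 was 1200 ± 45 against 1260 ± 125 (adjusted p = 0.928). In all, 172 genes changed, 117 higher and 55 lower, 18 of them TCR or immunoglobulin genes. Lilrb4a (3.01), Itgam (2.82), Il18rap (2.57), Myadm (2.49), Lgals3 (2.45), Itga7 (2.32), Lmna (2.27) and Il9r (2.12) rose. Gsta4 (-2.81), Tubb2a (-2.66), Gbp2b (-2.38), Jun (-2.09), Ly6c1 (-2.07), Gpr83 (-2.06), Treml2 (-1.99), Gata1 (-1.97), Rcn1 (-1.85) and Prg4 (-1.64) fell.

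The effector genes that rose (19 higher and 2 lower adjusted over the list alone) included Havcr2 (2.39), Rora (1.30) and Icos (1.15), and without WT spleen Treg replicate 2 the list had 6 genes higher and 1 lower (adjusted p = 0.283 with an estimated correlation). Of 19 lymphoid homing genes 4 fell, including Bcl2 (-1.48), Ccr7 (-1.23) and Foxp1 (-1.10), with an adjusted p = 0.0651 with an estimated correlation. Itgae (1.44) and Ccr4 (0.97) rose. Macrophage and monocyte genes were higher by a median of 1.56, with 1 of 16 passing (Itgam, and 3 adjusted over the list alone) and an adjusted p = 0.209 with an estimated correlation. Csf1r was 29.46 and 48.22 CPM in Tg and 4.53 and 21.54 in WT libraries, Ctss 340.14 and 272.32 against 318.12 and 350.89, and Lyz2 16.29 and 1.89 against 54.36 and 4. Without WT spleen Treg replicate 2 the list's median was 3.08 and 0 of 17 passed. Leaving out Tg replicate 1, Tg replicate 2 or WT replicate 2 lowered the count to 67, 57 and 59, and DESeq2 called 293. Tg and WT differed the same way in muscle and spleen for 11 genes higher and 13 lower, where independent lists would share 0.14 and 0.11. With TCR and immunoglobulin genes left out, a count added after seeing the data, 3 higher and 6 lower genes were shared, against 0.06 and 0.07.

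The comparison of injured with uninjured Tg mice asked whether distant muscle injury alters splenic Tregs. Icos was 601 ± 26.5 CPM against 686 ± 0.857 (SD, n = 2), Gzmb 181 ± 25.6 against 228 ± 28.7, Klrg1 437 ± 11.3 against 536 ± 128 and Foxp3 1200 ± 45 against 1160 ± 145. Named genes further apart included Col1a1 (6.41 ± 2.98 against 2.31 ± 1.81), Trbv13-1 (6.75 ± 2.5 against 14.4 ± 2.08) and H2-Ab1 (62.5 ± 17.7 against 35.5 ± 0.961), each with an adjusted p = 1. edgeR called 0 genes, with 236 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. Without a low-count filter 5 were called. The 236 are fewer than a share of 0.05 of the 13188 tested genes, so the test was conservative here. Chi-square per degree of freedom between libraries was 7.17 and 6.43 in these groups, against 35.7 in WT muscle Tregs of the same fit. The shared spread may be too wide here, and 0 calls do not show that the groups were alike. Macrophage and monocyte genes had a median of 0.62 with 15 of 16 positive and 0 passing (adjusted p = 0.322 with an estimated correlation), B cell genes a median of 0.80 with 9 of 10 positive and 0 passing (adjusted p = 0.508 with an estimated correlation), and effector genes a median of -0.24 with 5 of 28 positive and 0 passing (adjusted p = 0.508 with an estimated correlation). The 200 genes most clearly higher in WT muscle Tregs had a median log2 fold change of -0.08 here (camera p = 0.000474, and p = 0.283 with an estimated correlation), and the 200 lower genes 0.05 (p = 0.0964, and p = 0.428 with an estimated correlation). With the preset correlation, the higher genes did not pass without a low-count filter (camera p = 0.102), whereas the lower genes passed without a filter (camera p = 5.37e-06), with DESeq2 calls (camera p = 0.0433), with limma-voom calls (camera p = 0.0187) and with a replicate block (camera p = 0.0355).

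A test of the difference between the tissue effects in Tg and WT called 18 genes, 7 with a larger and 11 with a smaller log2 value in Tg. The IL-2 receptor gene Il2ra (1.50 ± 0.23) and Rel (1.33 ± 0.23) had a more positive muscle against spleen difference in Tg, as did Ly6c1, Gadd45g and Ecm1. The chemokine receptors Cxcr3 (-1.64 ± 0.29) and Ccr4 (-1.26 ± 0.23), as well as Lgals3 and Myadm, had a less positive one. Such a difference can arise in either tissue. In spleen Lgals3 (2.45), Myadm (2.49) and Ccr4 (0.97) were higher in Tg than in WT, and Il2ra (-0.91) and Ly6c1 (-2.07) lower. Cxcr3 was at 0.65 there (adjusted p = 0.19). In muscle Rel was higher in Tg (1.27). The smaller values of Lgals3 and Myadm thus do not show lower levels in Tg muscle. The count was 3 without injured Tg spleen Treg replicate 1 and 241 without WT muscle Treg replicate 1.

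Whole muscle 8 days after injury addressed the state of the regenerating tissue. The 4 genes that changed were all TCR genes, higher in Tg. Trac (chromosome 14, 54220521 to 54224206) was 66.5 ± 12.3 CPM in Tg against 0.271 ± 0.312 in WT (SD, n = 3), and Trav9-4 26 ± 6.93 against 0.0478 ± 0.0828. Trbc2 and Trbv13-2 had 0 counts in WT and were at least 14.4-fold and 8.68-fold higher in Tg against 3 counts per library, and the call of Trbv13-2 was lost when any 1 library was left out (adjusted p from 0.112 to 0.593). With a replicate block, and with a filter at 5 CPM, only 2 genes were called, Trac and Trav9-4 (with the block, adjusted p = 0.06 for Trbc2 and 0.37 for Trbv13-2), and without a filter 11 were called. Regenerating fibre genes had a median of 0.27 with 16 of 18 positive and 0 passing (adjusted p = 0.205 with an estimated correlation). Of these, Myh3 (227 ± 14.9 CPM in Tg, 224 ± 86 in WT; adjusted p = 0.998) and Actc1 (3560 ± 618 and 2680 ± 793; adjusted p = 0.994) did not pass, nor did Pax7 of satellite cells (1.85 ± 1.15 and 1.36 ± 0.872; adjusted p = 0.994), Acta1 (71400 ± 4580 and 73700 ± 5120; adjusted p = 0.994) or Col1a1 (1320 ± 191 and 1030 ± 342; adjusted p = 0.994).

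**Figure D2:**
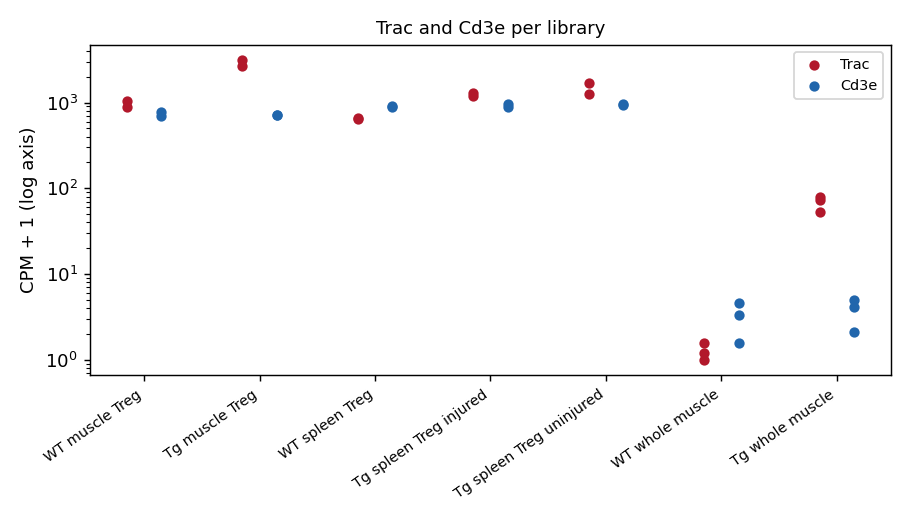
CPM plus 1 of Trac and of Cd3e, a T cell receptor complex gene, on a log axis, 1 point per library in each of the 7 groups. Trac in Tg whole muscle lies between 51.6 and 78.4 CPM, and Cd3e there between 1.13 and 3.95 CPM.

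Macrophage and monocyte genes were higher in Tg whole muscle by a median of 0.76 with 0 of 19 passing, such as Lyz2 (444 ± 44.5 against 262 ± 149 CPM), and an adjusted p = 0.497 with an estimated correlation. Matrix genes had a median of 0.36 with 0 of 25 passing and an adjusted p = 0.586 with an estimated correlation. WT whole muscle replicate 1 had the lowest level of both lists, and without it, an alternative chosen after seeing the data, the medians were 0.43 and 0.18.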

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

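The tests of the alpha chain in whole muscle, of the WT spleen library with high Igkc, of macrophage RNA and of chromosome positions were chosen after the results were seen.

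The muscle against spleen difference differed between Tg and WT Tregs, by a test of the difference itself, for 18 genes. It was more positive in Tg by 2.63 on the log2 scale for Ly6c1, 2.12 for Trbv13-2, 1.96 for Gadd45g, 1.79 for Ecm1, 1.65 for Trav9-4, 1.50 for Il2ra and 1.33 for Rel. It was lower for Igfbp4 (-6.45, a fitted value with 0 counts in Tg muscle), Myadm (-2.72), Lgals3 (-2.48), Nhsl2 (-2.21), Cxcr3 (-1.64), P2rx7 (-1.55), Ccr4 (-1.26), S100a10 (-1.24), Ahnak (-1.15) and Fam129a (-1.14, named only because it was called). For Trbv13-2 the muscle against spleen value was -1.71 in WT and 0.41 in Tg, and only Tg Tregs were gated on Vβ8.

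Trac and Trav9-4 in Tg whole muscle stood far above other T cell transcripts. If T cells carrying both transgenes brought them, Trbc2 would accompany Trac as in Tg Tregs, where the ratio of Trbc2 to Trac counts was between 2.23 and 5.67. In the Tg whole muscle libraries the highest ratio was 0.123, which argues against T cells like these as the whole source. Reads carried over from Treg libraries would keep the same ratio, and the upper 95% limit of the pooled ratio was 0.126. A candidate explanation is that the alpha chain transgene is transcribed outside T cells, and the pooled ratio of Cd3e to Trac was 0.0398 against 0.229 to 0.797 in Tg Tregs, but no test here names the cell, so this stays open.

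In splenic Tg Tregs 7 of 28 effector genes were higher than in WT ones, with 21 not passing and the list at an adjusted p = 0.0815 with an estimated correlation. RNA of macrophages or monocytes in the Tg sort would raise their markers. The median log2 fold change of the 16 tested list genes was 1.56, with 13 positive, so this remains a possible explanation for genes that such cells also express. Lyz2, however, was not higher (16.29 and 1.89 CPM in Tg, 54.36 and 4 in WT libraries). It varied widely within each genotype. C1qa was 12.94 and 15.37 CPM in Tg against 0.5 and 4.66 in WT, and C1qb 21.32 and 21.75 against 2.52 and 10.44. Adgre1 was 8.38 and 8.04 against 0.5 and 2.89, and Fcer1g 9.58 and 8.04 against 0.5 and 1.33. Cd74 was 148 ± 26.1 against 67 ± 30.9 CPM (adjusted p = 0.383). Of the list, 1 gene passed, and 3 adjusted over the list alone, all higher. Itgam and Lgals3 also rose in WT muscle against WT spleen Tregs (2.01 and 3.05), where the macrophage list's median was -2.04. These 2 genes can thus rise without such RNA, but whether it added to their rise in Tg spleen stays open. Leaving out the WT spleen library with high Igkc leaves 1 WT library, with the spread taken from other groups. The effector list's median was then 0.74 against 1.04 with both WT libraries. A part of that library in the difference stays open, because the loss of a replicate and the loss of this library cannot be told apart. The 200 genes higher in Tg muscle than in uninjured Tg spleen, from other libraries, had a median of 0.23 in Tg against WT spleen (camera p = 0.0482 with an estimated correlation). The 200 lower genes had a median of -0.34 (camera p = 0.00114 with an estimated correlation). Both medians go toward the muscle profile. That profile need not be a tissue state alone, because dissociation and heat shock genes also rose in Tg muscle. The signature test was not repeated without WT spleen Treg replicate 2. The sort gate and the clonal receptor differ together with genotype and were not tested apart.

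Of genes changed the same way in Tg against WT in muscle and spleen, 9 were no receptor genes: Ttn, Gm14085, Ccr7, Gbp2b, Prg4, Nckap5, Gpr83, Nav2 and Art2b. A single short chromosome segment of other origin would group them, but at most 1 lay in any window of 10 Mb. Each of 10000 random draws of tested genes also reached that number. With 9 genes and 1 window size, this cannot exclude a longer segment, several segments or a mixed background. Nckap5 and Prg4 shared chromosome 1, Ttn and Gm14085 chromosome 2, and Nav2 and Art2b chromosome 7.

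For whole muscle, 3 libraries against 3 give 10 splits, too few for a share under 0.05. The real split called 4 genes, as many as in 1 split with itself included, and the highest other split called 0. These 4 were the TCR genes that go with the transgene, so the genotype label fixed that outcome. Of other genes the real split called 0, so the splits give no support for a change in them.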

How the results depend on the processing

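List tests without 1 library and the robust form of limma-voom were chosen after seeing the data, and the cause of a change was not tested except where fewer genes or samples entered. The WT tissue count was 1046 with only the compared groups, 1323 with a log2 fold of at least 1, and 887 to 2768 without 1 library. The Tg tissue count was 452 to 640 without 1 library. For Tg against WT muscle Tregs it was 195 without a filter, 101 with DESeq2, 64 with robust limma-voom against 46 with the planned form, 16 without receptor segments (constant regions kept), 10 with only the compared groups, and 25 to 361 without 1 library. For Tg against WT spleen Tregs it was 372 without a filter, 293 with DESeq2, 338 with only the compared groups, and 57 to 160 without 1 library. Injured against uninjured spleen gave 5 without a filter and 0 to 0 without 1 library. The difference of tissue effects gave 140 without a filter, 63 with DESeq2, 4 without robust dispersion, 4 with only the compared groups, and 3 to 241 without 1 library. Whole muscle gave 11 without a filter, 2 at 5 CPM, 2 without receptor segments and 3 to 4 without 1 library. The shared-direction percent was 90.8 with either form of limma-voom, 94.1 after thinning and 87 to 95.7 without 1 library. In injured spleen, the median of genes higher in WT muscle was -0.079 without a filter, no longer passing, and -0.099 to -0.053 without 1 library. For genes lower in WT muscle it was 0.081 without a filter, 0.06 with DESeq2 and 0.068 with either form of limma-voom, each passing, and 0.01 to 0.104 without 1 library. Replicate numbers were not used as pairs, because the labels name nothing shared by number and same-numbered deviations correlated in some pairs of groups and not in others (from -0.068 to 0.19 in Tregs, where WT with Tg muscle had 0.19, WT with injured Tg spleen 0.141 and Tg muscle with injured Tg spleen 0.133, and from -0.062 to -0.021 in whole muscle). With a replicate block the counts were 2081, 1009, 40, 177, 0 and 14 in the Treg comparisons and 2 in whole muscle, and the median of genes lower in WT muscle was 0.055, now passing. With an estimated correlation 6, 5, 0, 0, 0 and 0 lists were called in the Treg comparisons and 0 in whole muscle. With fry 3 lists were called in Tg against WT muscle, 3 in Tg against WT spleen, and 0 in injured spleen, the difference of tissue effects and whole muscle. Without WT muscle Treg replicate 2, 11 lists against 7 were called in Tg against WT muscle, and without WT whole muscle replicate 1, 4 against 7 in whole muscle. With an estimated correlation, leaving out WT muscle Treg replicate 2 ended the call of the type 1 and cytotoxic list in WT tissue (adjusted p = 0.117) and added that of TCR-induced genes in Tg against WT muscle (adjusted p = 0.0187), and leaving out WT spleen Treg replicate 2 ended those of the type 1 and cytotoxic and the chemokine receptor and integrin lists in WT tissue (adjusted p = 0.0539 each) and added that of glycolysis (adjusted p = 0.0482). No called gene named in the text changed sign. Called genes kept their call in 729 of 734 values in WT tissue, 600 of 614 in Tg tissue, 251 of 313 in Tg against WT muscle, 376 of 450 in Tg against WT spleen, 187 of 302 for the difference of tissue effects and 54 of 64 in whole muscle. Some uncalled genes passed. In WT tissue these were Igkc with DESeq2 (-5.06), without robust dispersion (-5.03) and without WT spleen Treg replicate 1 (-6), S1pr1 after thinning (-0.49) and, without WT muscle Treg replicate 2, S1pr1 (-0.56), Rel (0.53) and Myc (-1.03), and Ctss without WT muscle Treg replicate 1 (0.53). In Tg tissue they were Klrg1 with planned limma-voom and without robust dispersion (1.14 each) and with only the compared groups (1.13), and Trbv13-2 without a filter (0.41), with robust limma-voom (0.42) and with only the compared groups (0.4). Some uncalled genes changed sign. Il2ra in WT tissue was -0.01 at 5 CPM and with either limma-voom, -0.02 after thinning and -0.09 to 0.16 without 1 library. Cd4 in Tg tissue was 0 without a filter, -0.01 at 5 CPM and with only the compared groups, and -0.07 to 0.08 without 1 library. Without 1 library, Lag3 (-0.04 to 0.88), Socs3 (-0.6 to 0.33), Ighm (-0.02 to 0.28), Igkc (-6 to 0.88) and Ctss (-0.33 to 0.53) in WT tissue, and Ctla4 (-0.11 to 0.33) and Ccr2 (-0.42 to 0.15) in Tg against WT muscle changed sign. So did Ctss (-0.3 to 0.02) and Foxp3 (-0.17 to 0.03) in Tg against WT spleen, Foxp3 in injured spleen (-0.07 to 0.17), and Myh3 (-0.2 to 0.36), Pax7 (-0.15 to 0.94) and Acta1 (-0.1 to 0) in whole muscle. Depth limits genes near 1.51 CPM in the shallowest library.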

Other observations

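Trac in WT Tregs was higher in muscle than in spleen (0.75 ± 0.15 on the log2 scale, adjusted p = 0.0037), and in Tg Tregs too (1.41 ± 0.15, adjusted p = 2.91e-05). Trav9-4, the leading Trav segment of Tg Tregs, rose in Tg muscle against injured Tg spleen (1.83 ± 0.14), whereas Trbv13-2 was at 0.41 ± 0.18 (adjusted p = 0.203). The ratio of Trbc2 to Trac counts was 2.48 and 2.23 in Tg muscle Tregs and 5.07 and 4.77 in injured Tg spleen Tregs.

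Igkc, an immunoglobulin light chain, was 1860 CPM in WT spleen Treg replicate 2 and between 15.6 and 63.3 CPM in the other 9 Treg libraries. Among Treg libraries, WT muscle Treg replicate 2 had the greatest depth (9116800 counts) and 0.072% of its counts in Gm10800, against 0.672 to 2.344% in the others.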
